A study of Mus musculus with 2 samples.

How the data were processed

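Chromatin carrying trimethylated lysine 36 of histone H3 (H3K36me3), a mark laid down on the bodies of transcribed genes, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in midbrain of mice on the day of birth. Per the labels, there were 2 biological replicates of 1 group, each from pooled male and female newborns of strain B6NTac;B6NCrl/Lap. Replicate 1 came from 15 mice and 1 technical replicate, and replicate 2 from a pool of unstated size and 2 technical replicates run on different sequencer models. With 1 group, no test between conditions was possible, and the replicates were compared with each other. The replicates are separate pools, so their spread covers pools of tissue and not single animals. The spread also holds the difference in size between their peak lists, which covered 88.4 Mb in replicate 1 and 60.7 Mb in replicate 2.

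Per the listing files deposited with each sample, the authors called peaks on filtered alignments to mm10 (GRCm38) against a control. They made 1 list per replicate, 1 list from the pooled alignments of both, and a replicated list derived from the pooled list and the per-replicate lists. The aligner, the peak caller and their settings were not given in the sources used here. All 99537 peaks of the replicated list were found in the pooled list at the same position, and 89.4% of those on the assembled chromosomes overlapped peaks of both replicates. Each deposited list gives, per peak, a fold enrichment (a linear ratio), a −log10 p and a −log10 q, as the authors' caller wrote them. These are the authors' own values per peak and were used only to describe, rank or filter peaks within a list. The smallest −log10 p in the deposited lists was 2.01 for replicate 1 and 2.04 for replicate 2, and the smallest −log10 q was 0.520 and 0.533, so the lists hold weak peaks as well as strong ones. Read depth was not given in the sources used here and is unknown, so no counting interval is given, and a gene without peaks was below the calling threshold at an unknown depth. A narrow-peak list cuts a broad mark into many short pieces, so the share of a gene under peaks depends on signal, depth and gene length together and is not a level of the mark.

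Gene spans, exons and gene types were taken from GENCODE release M21 for the same build, on chromosomes 1 to 19, X and Y. Peak ends were inside the chromosome lengths of the reference sequence. A protein-coding gene was called marked when at least 10% of its span, from the first to the last annotated base, lay under peaks of each replicate. Coverage was counted without regard to strand, so peaks in a gene that overlaps another may belong to either. Coverage of a gene is given as the mean over the replicates with its SD (n = 2), and the share under the replicated list as a single value.

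Peak locations were compared with 1000 random placements of the same peaks within their chromosomes, gaps left out. The smallest p that these could give was 0.001 one-sided and 0.002 two-sided. Promoters were taken as 1 kb on either side of a gene start. Positions within genes were compared in marked genes with spans of at least 10 kb, by 2-sided sign-flip permutation across genes with 100000 resamples, whose smallest p was 1e-05. The first exon and first intron were left out of the exon comparison. For regions beyond gene ends, marked genes of at least 10 kb with no other annotated gene within 20 kb were used. The numbers of marked genes in 35 gene lists were compared with 10000 random lists of equal size, matched on span length in 20 bins, by 2-sided permutation with Benjamini-Hochberg adjustment over the lists. The smallest p these could give was 0.0002, or 0.000875 after adjustment. The X chromosome was compared with the autosomes by 2-sided Fisher's exact test. Genes are not independent replicates, so every p across genes describes these peak lists and not a population of animals.

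The lists, the tests, the 10% rule and the genes to be named were fixed before the data were examined. Named genes were up to 2 marked members with the highest and 2 unmarked members with the lowest mean coverage per list, all members of 4 lists, the 10 long genes with the highest coverage, and the 5 in each direction with the largest rank difference between replicates. Named peaks were the 5 with the highest fold overall and the 5 with the highest fold more than 10 kb from any gene. Genes named outside this rule are said to be so. The alternatives were peaks with −log10 q of at least 2, equal numbers of peaks per replicate, the pooled list, each replicate left out, marking at 5% or 20%, genes overlapping no other gene, genes of at least 2 kb, overlap of at least 50% of a peak, all annotated genes, 5 kb windows and random lists without length matching. In these, 200 placements were drawn. A comparison of exons with intron bases within 500 bp was added after the data were seen.

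The statistics were tested on simulated peak lists with 3000 genes carrying peaks toward their 3′ ends. All 3000 were drawn from genes of at least 2 kb that overlap no other gene. Of the 3000, 100.0% were called marked, against 0.0229% of other genes overlapping no gene. Calls in genes that overlap another gene were not assessed. All 20 lists rich in such genes were called at an unadjusted p under 0.05, as were 5 of 200 random lists. Of 200 sign-flip tests without an effect, 15 were called at p under 0.05. Exon coverage exceeded intron coverage by 2.45 percentage points in the simulation although peaks were placed without regard to exons. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Peaks on unplaced or unlocalised scaffolds were left out of the gene comparisons.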

Results

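H3K36me3 was profiled in newborn mouse midbrain in 2 replicate pools, and the data consist of peak lists. Replicate 1 had 199150 peaks covering 88.4 Mb (mean width 444 bp), and replicate 2 had 161963 peaks covering 60.7 Mb (mean width 375 bp). The replicated list held 99537 peaks over 71.6 Mb, or 2.71% of the ungapped genome, with a mean width of 720 bp. The median fold enrichment given by the authors was 3.38 in replicate 1, 3.47 in replicate 2 and 3.84 in the replicated list.

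The first comparison asked how far the replicates marked the same places and genes. Some genes differed little between the replicates and others more, as with Snrnp200, which had 80.2% of its span under peaks in replicate 1 and 59.4% in replicate 2. Eef2, which encodes a translation elongation factor (chromosome 10, 81176631 to 81182498), had 58.0% ± 4.5 of its span under peaks (SD, n = 2), and Polr2a, the large subunit of RNA polymerase II (chromosome 11, 69733997 to 69758637), had 42.6% ± 4.3. Shank1, a postsynaptic scaffold gene, had 41.9% in replicate 1 and 42.0% in replicate 2. Slc6a1, which encodes a GABA transporter, had 29.6% ± 0.059. Across 21938 protein-coding genes, Spearman's rho between the replicates was 0.929 and Pearson's r was 0.936; these are correlations across genes.

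Of the replicate 1 peaks, 53.7% overlapped a replicate 2 peak by at least 1 bp, and 71.8% of the replicate 2 peaks overlapped a replicate 1 peak. The Jaccard index of covered bases was 35.9%, against a mean of 1.60% and a highest value of 1.66% in random placements of the replicate 2 peaks (permutation p = 0.001, one-sided, the smallest they can give). Peaks of replicate 1 that met no replicate 2 peak were weaker, with a median fold of 3.12 against 3.85 and a median width of 242 bp against 428 bp. When at least 50% of a peak had to be shared, 37.1% of replicate 1 peaks and 60.7% of replicate 2 peaks overlapped.

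Of 21938 protein-coding genes, 6242 (28.5%) were marked in both replicates, 1421 in replicate 1 alone and 247 in replicate 2 alone. A further 9020 genes (41.1%) held no peak in either replicate. Marked genes held 78.7% of the bases of replicated peaks on the assembled chromosomes, and their median coverage was 32% in the replicated list. Of genes with spans of 10 to 50 kb, 40.2% were marked, against 3.72% below 2 kb and 3.51% above 200 kb. The count of marked genes fell to 3861 when 20% coverage was required.

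Ints1, Fasn and Scrib led the genes of at least 10 kb by replicated coverage. Ints1, a subunit of the Integrator complex that processes small nuclear RNAs (chromosome 5, 139751282 to 139775674), had 80.4% ± 1.4 of its span under peaks and 87.7% under replicated peaks. Fasn, the fatty acid synthase (chromosome 11, 120805846 to 120824547), had 82.5% ± 1.1. Scrib, a cell polarity scaffold (chromosome 15, 76047158 to 76069784), had 77.6% ± 6.7, and Kmt2b, a histone H3 lysine 4 methyltransferase (chromosome 7, 30568858 to 30588726), had 77.2% ± 5.0. Rnf40, part of the ubiquitin ligase for histone H2B, had 75.5% ± 0.29. Zfp335, Drg2, Katnb1, Tfip11 and the 137 kb gene Ubr4 completed the first 10, with replicated coverage from 82.3% in Ubr4 to 83.6% in Zfp335.

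The 5 genes in each direction whose rank differed most between replicates had peaks in 1 replicate only, covering at most 17.9% of the span. C1d, a cofactor of the RNA exosome, had 17.9% of its span under peaks in replicate 1 and 0% in replicate 2, and Prdx3, a mitochondrial peroxiredoxin, had 15.8% and 0%. 1110032A03Rik, Casp6 and Zfp300 likewise had peaks in replicate 1 only, with 14.6%, 14.5% and 12.4%. In the other direction, Mfge8 had 10.5% in replicate 2 and 0% in replicate 1, and Nr2f1, a nuclear receptor of the developing brain, had 9.80% and 0%. The mitotic genes Kif2c and Cenpm and the gene Als2cl had 8.40%, 5.98% and 6.93% in replicate 2 alone. Over 14164 genes of at least 10 kb, the median rank difference was 2.54 percentile points and 874 genes differed by more than 20 points. With 1 pool on each side, no gene was tested between replicates.

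**Figure D1:**
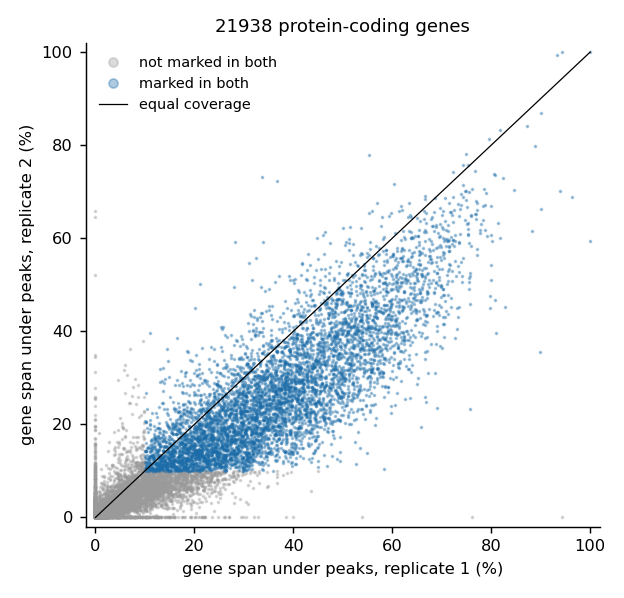
Share of each protein-coding gene's span under peaks in replicate 1 (horizontal, %) and replicate 2 (vertical, %), 1 point per gene, with the 6242 genes marked in both replicates in blue and a line at equal coverage. Most marked genes lie below the line, and their median coverage was 35.3% in replicate 1 and 24.6% in replicate 2.

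The second comparison asked where in the genome the mark lay. Protein-coding gene spans held 95.9% of the bases of replicated peaks, against 42.2% in random placements (permutation p = 0.002, two-sided, the smallest they can give), and 94.8% ± 0.45 in the replicates' own lists (SD, n = 2). Exons held 27.7% of replicated peak bases against 4.04% in placements, and introns 68.2% against 38.1%. Promoters held 0.413% against 1.73%, and regions outside any annotated gene 3.50% against 50.9% (each permutation p = 0.002, two-sided).

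Of the 5 strongest peaks, 4 lay in zinc finger genes. The highest fold, 11.8, was a 3546 bp peak in Zfp354c (chromosome 11, 50812937 to 50816482), of which 3057 bp were exonic. Peaks in Zfp110 (chromosome 7, 12844037 to 12849497, fold 10.3), Zfp157 (chromosome 5, 138455435 to 138459322, fold 9.22) and Zfp518b (chromosome 5, 38670941 to 38675199, fold 9.20) came next, followed by a mostly intronic peak in Rapgef1 (chromosome 2, 29702005 to 29705399, fold 9.04). Only 59 replicated peaks lay more than 10 kb from every annotated gene. The strongest of them was on chromosome 10 (100164260 to 100165204, fold 5.92), with Kitl, 63843 bp away, as the nearest protein-coding gene. The others were on chromosome 6 (125441652 to 125442552, fold 5.57, nearest Cd9), chromosome 8 (89001957 to 89002956, fold 5.26, nearest protein-coding gene Sall1), chromosome 10 (79053056 to 79053460, fold 5.22, nearest 2610008E11Rik) and chromosome 9 (56072641 to 56072969, fold 4.87, nearest Rcn2).

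The third comparison followed the mark along genes. In 4741 marked genes of at least 10 kb, replicated peaks covered 2.86% of the first of 10 equal parts of the span, 35.5% of the fifth, 52.9% of the ninth and 49.3% of the last. Mean coverage of the 5′ side was 20.9% and of the 3′ side 47.2%, a difference of 26.3 percentage points (sign-flip permutation p = 1e-05, two-sided, the smallest it can give). It was 25.6 points in replicate 1 and 19.9 points in replicate 2. Coverage was higher on the 3′ side in 88.4% of the genes.

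**Figure D2:**
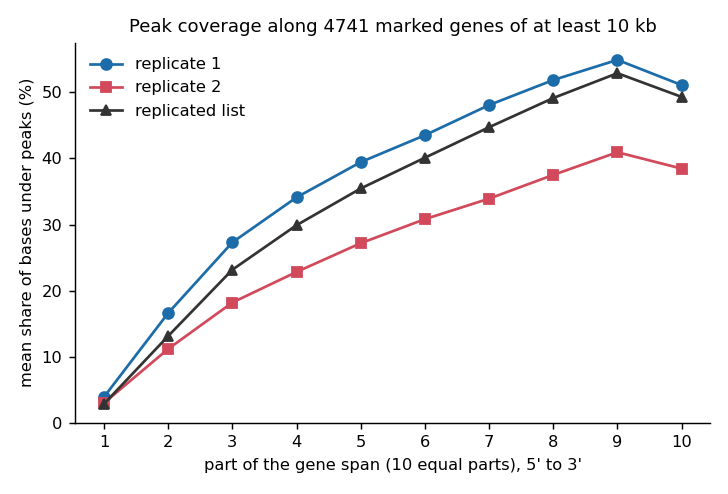
Mean share of bases under peaks (vertical, %) in each of 10 equal parts of the gene span from 5′ to 3′ (horizontal) in 4741 marked genes of at least 10 kb, with 1 line for each replicate and 1 for the replicated list. All 3 lines rise from under 4% in the first part to their highest value in the ninth.

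Exons were covered more than introns of the same genes. In 4713 marked genes, replicated peaks covered 54.0% of exon bases and 37.9% of intron bases, a difference of 16.1 percentage points (sign-flip permutation p = 1e-05, two-sided, the smallest it can give), with exons higher in 79.2% of the genes. The difference was 14.0 points in replicate 1 and 14.1 points in replicate 2. It fell to 6.23 points against intron bases within 500 bp of an exon, a comparison added after the data were seen. Peaks simulated without regard to exons gave 2.45 points in the first comparison, the one that gave 16.1 here. The comparison with nearby intron bases was not simulated.

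Replicated peaks went on past annotated 3′ ends and were absent ahead of 5′ ends. In 127 marked genes standing apart from other genes, replicated peaks covered 5.11% of the 10 kb after the gene end and 0% of the 10 kb before its start (sign-flip permutation p = 1e-05, two-sided, the smallest it can give). Downstream coverage was higher in 73 genes, upstream coverage in 0, and 54 genes had no peak on either side. The replicates' own lists gave 6.71% and 4.92% downstream, and 0.106% and 0.119% upstream. Coverage was 26.7% in the first kb past the end, 12.4% in the second and 0.475% in the last. Itm2b, a transmembrane gene (chromosome 14, 73362226 to 73385289), had the highest downstream coverage, 37.2%, followed by Cops8, a COP9 signalosome subunit, with 27.4%, Frg1 with 22.3% and the neuronal gene Stmn2 with 20.4%. These 4 genes were picked after their values were seen.

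**Figure D3:**
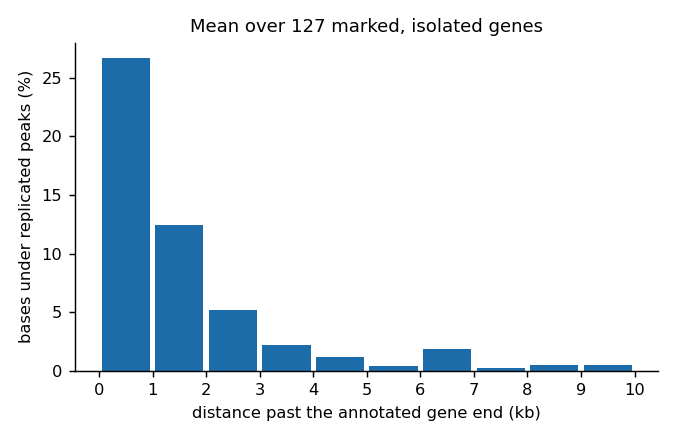
Mean share of bases under replicated peaks (vertical, %) in each kb past the annotated end (horizontal) of 127 marked genes with no other gene within 20 kb. Bars fall from 26.7% in the first kb to 1.21% in the fifth.

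The fourth comparison asked which kinds of genes were marked, with 35 lists of genes. Marked members were more frequent than in length-matched random lists in 8 lists, less frequent in 5, and did not pass the adjusted threshold in 22.

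Genes of basic cell functions were marked often. Of 34 spliceosome genes, 29 were marked against 11.8 in random lists (Benjamini-Hochberg adjusted permutation p = 0.000875, the smallest possible). Prpf8, the core of the spliceosome, had 74.3% ± 6.5 of its span under peaks (SD, n = 2) and Snrnp200, an RNA helicase, had 69.8% ± 14.7, while Srsf2 (10.7% ± 3.7) and Snrpd1 (12.3% ± 7.7) reached 10% in 1 replicate only. Of 25 oxidative phosphorylation genes, 20 were marked against 8.04 (adjusted permutation p = 0.000875), led by Uqcrc1 with 59.9% ± 8.1 and Ndufa10 with 59.7% ± 15.1, while Cox7c had 0%. Of 71 ribosomal protein genes, 47 were marked against 12.7 (adjusted permutation p = 0.000875). Rps3 had 60.2% ± 5.5 and Rps5 56.7% ± 14.2, and there was no peak in Rplp1 or the X-linked Rpl10. Of 21 reference genes used to normalise expression, 15 were marked against 6.56 (adjusted permutation p = 0.00233). B2m (0%) and the X-linked Hprt (1.86% ± 1.69) were not. The reference list did not pass with strong peaks only (adjusted permutation p = 0.121) or at 20% coverage (adjusted permutation p = 0.0999).

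Enzymes and binding proteins of H3K36 methylation carried the mark themselves. Of 19 such genes, 15 were marked against 5.83 (adjusted permutation p = 0.000875). Setd2, the methyltransferase that makes H3K36me3 (chromosome 9, 110532597 to 110618633), had 24.7% ± 9.6 of its span under peaks. Nsd1, Nsd2 and Nsd3, which make the lower methylation states, had 28.8% ± 12.8, 29.2% ± 10.9 and 25.4% ± 6.5, and the demethylases Kdm4a and Kdm4b had 69.5% ± 11.7 and 43.8% ± 3.4. The DNA methyltransferase gene Dnmt3a was marked with 29.7% ± 1.7, and Dnmt3b was not, with 4.94% ± 0.47. Supt6 and Iws1, which travel with the polymerase, had 59.4% ± 5.4 and 31% ± 10.6, whereas Phf19 had 0%. Of the other members, Brpf1 had 57.1% ± 11.9, Psip1 32% ± 14.8, Ash1l 26.7% ± 8.6, Morf4l1 19.9% ± 14.0, Kdm2a 18.2% ± 10.2 and Zmynd11 14.9% ± 4.3, and Kdm2b (9.25% ± 0.80) and Kdm4c (6.29% ± 4.59) were not marked. Only 3 members overlap no other gene; all 3 were marked, which did not pass (adjusted permutation p = 0.153).

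Of 391 genes named Zfp, most of them zinc finger transcription factors, 220 were marked against 139 (adjusted permutation p = 0.000875). Zfp869 had 74.9% ± 18.9 of its span under peaks and Zfp335 73.4% ± 9.2, while Zfp114 and Zfp119b had 0%. Of 57 clustered protocadherins, cell-surface genes in a tandem array on chromosome 18, 21 were marked against 10.7 (adjusted permutation p = 0.0035). Pcdhgc5 had 29.1% ± 1.5 and Pcdhgc4 24.6% ± 0.76, while Pcdhb1 and Pcdhb10 had 0%. All 57 overlap other annotated genes, so they do not count as separate genes, and the excess turned to a deficit of 4.94 genes with strong peaks only (adjusted permutation p = 0.132) and of 3.44 at 20% coverage (adjusted permutation p = 0.31). The call was also lost with equal numbers of peaks (adjusted permutation p = 0.217), by replicate 1 alone (0.115), at 5% coverage (0.226) and without length matching (0.311). Of 41 synapse and ion channel genes, 15 were marked against 7.76 (adjusted permutation p = 0.0216), among them Nlgn2 with 43.6% ± 3.8 and Shank1 with 41.9% ± 0.087. Kcna1 had 0% and the X-linked Gria3 0.0333% ± 0.047. The list did not pass by replicate 1 alone (adjusted permutation p = 0.0667), with strong peaks only (0.0835) or with equal numbers of peaks (0.0947). Nor did it pass in genes overlapping no other gene (adjusted permutation p = 0.212) or without length matching (0.402).

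Dopaminergic genes, which define the best-known neurons of the midbrain, were not marked. None of 16 members reached 10%, against 4.79 in random lists (adjusted permutation p = 0.0222), and 11 had no peak in either replicate. Th, which encodes the rate-limiting enzyme of dopamine synthesis (chromosome 7, 142892752 to 142931128), had 0% of its span under peaks in both replicates, as did the dopamine transporter gene Slc6a3, the transcription factor genes Nr4a2, Pitx3, Foxa1, Foxa2, Lmx1b and En1, and Ddc, Gch1 and Aldh1a1. The highest values were 4.56% ± 1.03 in Ret, a receptor kinase gene, and 2.94% ± 4.15 in En2. Slc18a2 had 0.605% ± 0.091, Drd2 0.449% ± 0.030 and Lmx1a 0.0643% ± 0.0909. The call did not hold with strong peaks only (adjusted permutation p = 0.0717), at 20% coverage (0.25) or in the 9 members overlapping no other gene (permutation, 0.387).

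Marking of pan-neuronal genes was not separated from that of random lists, with 9 of 22 against 5.6 (adjusted permutation p = 0.19). Of the 22 members, 19 overlap another annotated gene, and 1 of the 3 that overlap none was marked. Atp1a3, the neuronal sodium pump subunit, had 58.6% ± 9.0, Uchl1, a ubiquitin hydrolase, 46.0% ± 9.4, and Stxbp1, needed for synaptic vesicle release, 38.5% ± 5.6. Elavl3 had 25.7% ± 3.8, the tubulin gene Tubb3 23.4% ± 3.9, Stmn2 22.7% ± 6.2, Mapt 21.7% ± 3.6, Ina 18.8% ± 6.1 and Kif5c 17.6% ± 5.0. The other members were not marked: Ncam1 had 10.9% ± 2.0, Ank2 7.62% ± 3.69, Map2 7.17% ± 3.27, Nefl 6.95% ± 3.28, Elavl4 5.93% ± 3.49, Nefm 2.37% ± 1.92, Rbfox3 1.30% ± 0.38 and Syt1 0.906% ± 0.136. Snap25 had 3.33% ± 1.58, Gap43 3.86% ± 2.45 and the X-linked genes Syp, Syn1 and Dcx 12% ± 9.0, 3.74% ± 1.27 and 1.73% ± 0.87. Of 37 axon guidance and adhesion genes, 8 were marked against 5.66 (adjusted permutation p = 0.427), with Plxna1 at 65.4% ± 9.3 and the X-linked Plxna3 at 31.1% ± 5.3, and Sema3a at 0%.

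Midbrain and hindbrain patterning genes were unmarked, with 0 of 13 against 3.23 (adjusted permutation p = 0.0817). The list passed by replicate 1 alone (adjusted permutation p = 0.0238) and at 5% coverage (0.0175). It shares En1, En2 and Lmx1b with the dopaminergic list, so the 2 lists are not separate results. Otx2 had 1.67% ± 2.36, Meis2 0.373% ± 0.374, Pax7 0.323% ± 0.457, Pax3 0.238% ± 0.337 and Pax5 0.056% ± 0.0792, and Wnt1, Fgf8, En1, Pax2, Otx1 and Dmbx1 had 0%. No gene of the 39 Hox genes was marked against 8.71 (adjusted permutation p = 0.000875), a call not held in the 16 that overlap no other gene (adjusted permutation p = 0.44), and 38 of them had no peak. Forebrain factors such as Dlx1 and Dlx2 had 0 of 14 marked against 3.58 (adjusted permutation p = 0.068), and passed by replicate 1 alone (adjusted permutation p = 0.0238), by replicate 2 alone (0.0465) and at 5% coverage (0.0198). Markers of other neuron types gave 1 of 12 for GABAergic genes (expected 3.61, adjusted permutation p = 0.202), 0 of 8 for glutamatergic genes (2.35, adjusted permutation p = 0.178), 0 of 8 for serotonergic and noradrenergic genes (2.29, adjusted permutation p = 0.178) and 0 of 6 for cholinergic genes (1.74, adjusted permutation p = 0.302). The 1 marked GABAergic gene was Slc6a1; Gata2, Helt, Barhl2, Pou4f1, Dbh, Fev, Isl1 and Mnx1 had 0%.

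Lists of glia and other cells of the tissue did not pass the adjusted threshold. Of the marked genes named here, Msi1, Notch1, Mcm7, Ccna2, Glul, Cnp, Hexb and Slc2a1 overlap other annotated genes, and Clu and Cd68 do not. Of 13 progenitor and radial glia genes, 2 were marked against 3.02 (adjusted permutation p = 0.81), Msi1 with 30.8% ± 1.6 and Notch1 with 10.3% ± 0.19, whereas Fabp7 and Hes1 had 0%. Of 25 cell cycle genes, 7 were marked against 8.75 (adjusted permutation p = 0.68), including Mcm7 with 30.4% ± 10.5 and Ccna2 with 28.4% ± 19, and Aurkb and Birc5 had 0%. Of 11 astrocyte genes, 2 were marked against 3.36 (adjusted permutation p = 0.68), Glul with 40.4% ± 9.2 and Clu with 19.9% ± 4.6, and Gfap and Aqp4 had 0%. Of 11 myelin genes, 1 was marked against 4.14 (adjusted permutation p = 0.145), Cnp with 53.0% ± 1.2, and Mag and Cldn11 had 0%. Of the 7 myelin genes overlapping no other gene, 0 were marked. Oligodendrocyte precursor genes, Olig1 and Gpr17 among them, gave 0 of 7 against 2.07 (adjusted permutation p = 0.205). Of 15 microglial genes, 3 were marked against 3.85 (adjusted permutation p = 0.897), led by the 1.94 kb gene Cd68 with 82.6% ± 19.5, followed by Hexb with 17.1% ± 1.1, and C1qa and C1qb had 0%. Endothelial and pericyte genes gave 1 of 15 against 4.33 (adjusted permutation p = 0.139), the glucose transporter gene Slc2a1 with 13.1% ± 0.63, and Cldn5 and Cdh5 had 0%; this list alone passed in alternatives, by replicate 1 alone (adjusted permutation p = 0.0292) and at 5% coverage (0.0198).

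Genes of other organs were unmarked almost throughout. Olfactory receptor genes had 1 of 1093 marked against 262, Olfr692 with 21.1% ± 3.7, and vomeronasal receptor genes had 0 of 327 against 94.4 (each adjusted permutation p = 0.000875). Liver genes such as Alb and Ahsg had 0 of 15 against 4.55 (adjusted permutation p = 0.0248), which did not pass with strong peaks only (0.0717), at 20% coverage (0.171) or in genes overlapping no other gene (0.176). Skeletal muscle genes, Acta1 and Ckm among them, had 0 of 15 against 3.32 (adjusted permutation p = 0.0753), epithelial genes such as Cdh1 and Cdx1 0 of 12 against 3.50 (adjusted permutation p = 0.0753), erythroid genes such as Hba-a1 and Gypa 0 of 10 against 2.37 (adjusted permutation p = 0.178), and germline genes 1 of 16 against 4.97 (adjusted permutation p = 0.0753), where Acr had 16.6% ± 2.2 and Dazl and Mael 0%. The muscle, epithelial and germline lists passed by replicate 1 alone (adjusted permutation p = 0.0238, 0.0241 and 0.0238) and at 5% coverage (adjusted permutation p = 0.0198, 0.0198 and 0.0183), and the muscle list also without length matching (0.0339). Immediate early genes gave 2 of 12 against 2.70 (adjusted permutation p = 0.94), Npas4 with 32.4% ± 3.2 and Nr4a1 with 18.7% ± 5.6, and no peak in Arc or Egr3. Imprinted protein-coding genes gave 6 of 26 against 7.22 (adjusted permutation p = 0.81), led by Nnat with 41.7% ± 9.6 and Igf2r with 37.4% ± 8.8, with Asb4 and Calcr at 0%. Of 69 histone genes, 1 was marked against 4.15 (adjusted permutation p = 0.178), and without length matching the deficit grew to 18.7 genes and passed (adjusted permutation p = 0.0007). That gene, H13, encodes a signal peptide peptidase and met only the naming pattern of the list, and Hist1h1a had 0%.

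**Figure D4:**
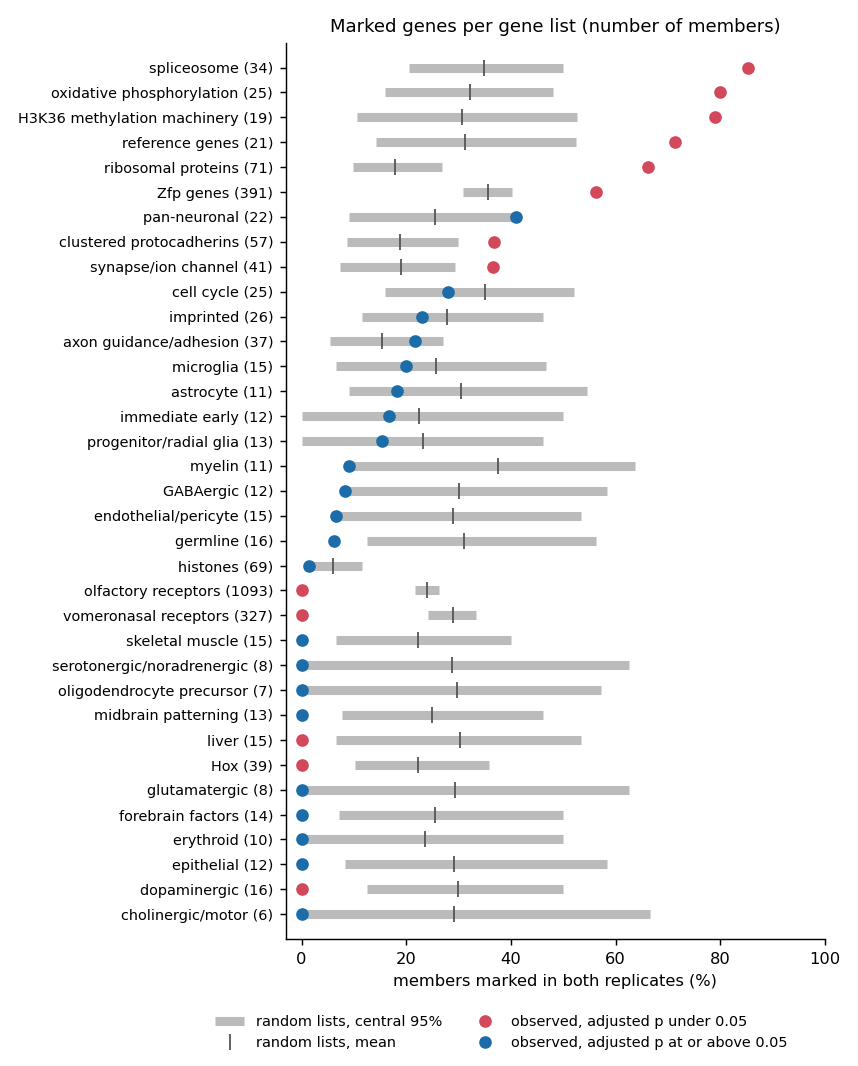
Share of each list's members marked in both replicates (points, %), with the mean (tick) and central 95% (grey bar) of 10000 length-matched random lists; the number of members is in parentheses and red points have an adjusted p under 0.05. Spliceosome genes reached 85.3%, and dopaminergic genes lay at 0%, as did several other lists.

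The fifth comparison set the X chromosome against the autosomes. On X, 36 of 948 protein-coding genes (3.8%) were marked, against 6206 of 20807 (29.8%) on the autosomes (odds ratio 0.0929, two-sided Fisher's exact p = 1.65e-91, across genes). The autosomes ranged from 19.2% on chromosome 14 to 38.9% on chromosome 8, and none of the 183 genes on Y was marked. Replicated peaks numbered 3.13 per Mb on X and between 25.7 per Mb on chromosome 3 and 66.0 per Mb on chromosome 11 among the autosomes. Replicate 1 alone marked 9.28% of X genes and replicate 2 alone 3.90%, against 36.4% and 31% of autosomal genes, and the X share was 1.90% with strong peaks only, 7.07% at 5% coverage and 0.949% at 20%.

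The X genes with the highest replicated coverage, named after their values were seen, were Flna, an actin crosslinker, with 40.0% ± 11.3 of its span under peaks over the replicates (SD, n = 2), Kdm5c, a histone demethylase, with 29.4% ± 17.5, and Hcfc1, a transcriptional coregulator, with 32.2% ± 15.0. Maged1 had 33.9% ± 8.7 and Maged2 30.4% ± 2.6. The metabolic genes Hprt and Pgk1, the second also named after the data were seen, had 1.86% ± 1.69 and 10.1% ± 5.9 and were not marked. Sex ratios of the pools were not given in the sources used here.

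**Figure D5:**
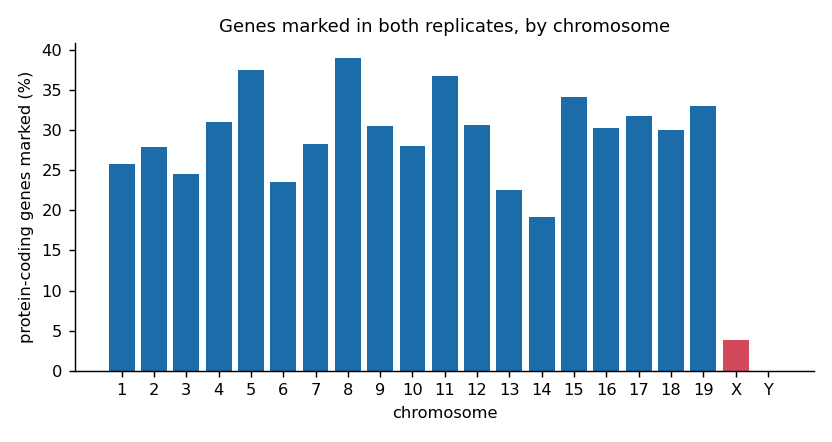
Share of protein-coding genes marked in both replicates (vertical, %) on each chromosome (horizontal), with the sex chromosomes in red. X stands at 3.8%, below the lowest autosome, chromosome 14, at 19.2%.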

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

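The replicated list held 5 peaks on unplaced or unlocalised scaffolds, which the gene comparisons left out. They are listed because they number more than 3, a limit set for reporting and not a test. Each replicate's own list held 14. The 5 replicated peaks lay on scaffolds assigned to chromosomes 4 and X and had folds of 3.31 to 6.27 in the authors' list.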

How the results depend on the processing

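Of 58 values of the main results under the alternatives, 50 kept their direction and their side of the threshold, stayed within 1.5 times for counts, or, for correlations, stayed within the approximate 95% interval of the main value. Marked genes numbered 3861 at 20% coverage, by construction from a higher bar. Among the 11725 genes overlapping no other gene, 2719 were marked. The number is lower by construction from fewer genes, but the share was lower too, 23.2% against 28.5% of all protein-coding genes. The lists past the threshold fell from 13 to 8 with strong peaks only (−log10 q of at least 2) and to 7 among genes overlapping no other gene, and were 18 at 5% coverage, 9 at 20%, 11 with equal numbers of peaks and 14 to 17 with a replicate left out. Spearman's rho was 0.921 with strong peaks, 0.926 with equal numbers of peaks, 0.919 among genes overlapping no other gene and 0.934 among genes of at least 2 kb. With each replicate left out, the share of peak bases in protein-coding genes was 94.5% to 95.1% and 6489 to 7663 genes were marked. Of 279 values of single lists, 238 were the same, 19 lost and 15 gained significance. The excess of marked protocadherins turned to -4.94 with strong peaks and -3.44 at 20% coverage. Lists that never passed also changed sign: astrocyte genes (0.0363) and immediate early genes (0.555) among genes overlapping no other gene, immediate early genes with a replicate left out (-1.30 to 0.0575), imprinted genes at 20% (0.0622) and axon guidance genes without length matching (-2.53). The cause was not tested. 6 lists passed under all 9 settings: ribosomal, oxidative phosphorylation, spliceosome, olfactory, vomeronasal and Zfp genes. Of 218 values of the 109 named genes with any peak, with strong or equal numbers of peaks, 168 moved by no more than the SD between replicates. That SD also holds the difference in size between the 2 peak lists. Depth was unknown, so genes without peaks cannot be called free of the mark.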

Other observations

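The tests in this part were planned after the main counts were known but before their own results were seen, except the test of neuron-type markers, which was chosen after its counts were seen. After their results were seen, the criterion of the test of neighbouring Zfp genes was loosened and that of the test of broadly used X genes was tightened. The genes named in the next 2 paragraphs were chosen after the data were seen. Rps4x and Eif2s3x, named with the X tests below as members of the tested sets, lie outside the naming rule.

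Long intergenic non-coding RNA genes outside protein-coding spans were seldom marked. Of 5358, 34 (0.635%) had at least 10% of their span under peaks in both replicates, against 28.5% of protein-coding genes, without matching on length. Other kinds differed, with 4.12% of 340 processed transcripts, 2.95% of 916 microRNA genes, 18.2% of 11 sense intronic genes and 0% of 852 small nuclear RNA genes. Marked microRNA genes were so short that a single peak can cover the whole span. Most of them lay in the chromosome 12 cluster described next, so they do not count as separate places. In the maternally expressed imprinted cluster on chromosome 12, Meg3 (109541001 to 109571726) had 55.6% of its span under peaks in replicate 1 and 42.9% in replicate 2, Mirg had 39.7% and 39.2%, and Rian had 29.1% and 14.2%. Malat1, an abundant nuclear RNA, had 28.1% and 19.5%, and Miat had 28.8% and 17.2%. Neat1 had 1.21% and 5.0%, Xist 2.46% and 0.848%, and H19 had 0% in both.

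Of the 10 replicated peaks with the highest fold, 5 lay in Zfp genes, as did 21 of the first 100 and 1.92% of all 99532 on the assembled chromosomes.

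Few X genes were marked. Whether the kinds of genes on X account for it stays open. Of broadly used genes in the reference, ribosomal, oxidative phosphorylation, spliceosome and H3K36 lists, 0 of 4 on X (Hprt, Pgk1, Rpl10, Rps4x) and 125 of 165 on autosomes were marked (two-sided Fisher's exact p = 0.00414). This met the criterion set beforehand against the explanation, before it was tightened to ask for each replicate alone. By replicate 2 alone, 0 of 4 and 127 of 165 were marked (two-sided Fisher's exact p = 0.00341). By replicate 1 alone, 2 of 4 and 145 of 165 were (two-sided Fisher's exact p = 0.0827), and 4 genes are few. The called peaks on X were also weaker. The median fold of its 536 replicated peaks was 3.31 against 3.84 on autosomes, below all 10000 random sets of autosomal peaks (lowest 3.66). Those sets drew peaks singly, whereas peaks lie together in genes. Few peaks and weak peaks may be the same observation, so a lower signal as the cause stays open. A silenced X copy in female cells as a source of lower signal stays open too. Of 6 genes that escape X inactivation, 2 were marked (Kdm5c and Eif2s3x), against 0 of the 4 others (two-sided Fisher's exact p = 0.467). Fewer X copies in a mixed-sex pool were not told apart from silencing, and no biological group in the design bears on it.

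Replicate 1 marked 1421 genes alone and replicate 2 247. Of those 1421 genes, 93.5% held at least 1 peak of replicate 2, against 31.4% of genes marked by neither, which is consistent with fewer or narrower calls in these genes. In the other direction, 75.7% of the 247 genes held a peak of replicate 1. The number of peaks alone leaves the matter open: with equal numbers, replicate 1 still covered 78.9 Mb against 60.7 Mb, and the ratio of genes marked alone was 2.66, compared with 5.75 as called. Depth was unknown, and differences between the pools of animals were not tested.

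Zfp genes were marked often. The excess was also found away from other protein-coding genes named Zfp, so reads shared between such neighbours alone do not account for it. Zfp genes with no other Zfp gene within 100 kb were marked in 55.6% (94 of 169, against 55.9 genes in random lists, permutation p = 0.0002, the smallest possible). Those with a neighbour were marked in 56.8% (two-sided Fisher's exact p = 0.838). Zinc finger genes under other names and pseudogenes did not count as neighbours. The criterion set beforehand also asked for no lower share in the first group, which was not met; it was replaced, once this was known, by no detectable difference, because an excess without neighbours is what sharing between neighbours cannot give. Overlap with other genes does not account for it either: 57.0% of the 223 Zfp genes overlapping none were marked, 127 against 68.2 (permutation p = 0.0002). Reads shared between distant copies, or with near copies under other names, stay open. No biological explanation was tested, since the design has 1 group.

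A hypothesis for the low coverage of dopaminergic genes is that genes used by a minority of cells fall below the calling threshold in whole tissue. Markers of single neuron types were marked in 1 of 50 cases (Slc6a1) and pan-neuronal genes in 9 of 22 (two-sided Fisher's exact p = 4.76e-05). The hypothesis stays open, because the lists were pooled after their counts were known, so that this test cannot support it, and the cell numbers were not measured.

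Peak positions within genes recurred between the replicates beyond what the choice of gene spans gives, with overlapping spans merged. Peaks of replicate 1 covered 66.0% of the bases of replicate 2 peaks lying inside protein-coding spans. Those peaks were shifted within the same merged spans 200 times. The mean was then 31.8% and the highest value 32.5% (permutation p = 0.00498, one-sided, the smallest possible). A hypothesis that positions follow the merged span alone was thus not borne out. A shift could move a peak into an overlapping gene, so the choice of gene within a merged span was not held fixed. The slope toward 3′ ends, exons and uneven read mappability are among the features that were not separated here.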
